A study of Arabidopsis thaliana with 3 samples.

How the data were processed

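The samples were 3 two-colour arrays of Arabidopsis thaliana opr3-3 coi1-1 seedlings. Per the labels' protocols, seeds were germinated on Johnson medium with 0.5 µM coronatine, which selects coi1-1 homozygotes, at 21 °C with 16 h of light and 8 h of dark. At 9 days, 20 seedlings per sample were moved to liquid with or without 50 µM OPDA and collected 1 h later. About 100 mg of tissue was extracted and 200 ng of total RNA was amplified and labelled. The mock sample carried the red dye (Hy5) and the OPDA sample the green dye (Cy3) on replicates 1 and 3, and the dyes were the other way round on replicate 2. All 3 arrays lay on 1 slide, so slide could not be tested as a batch.

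The deposited scanner files hold spot intensity values of both channels on a linear scale, made by Agilent Feature Extraction 10.7.3.1, per the file headers. The files also give flags for outliers, saturation and signal well above background, and a log10 ratio of red over green after background subtraction and dye normalization, per the file headers. The deposited value table of the series holds log2 ratios with an unstated method. Set against the scanner values, its columns correlated at 0.985, 0.986 and 0.981 with the log2 change of OPDA over mock, which gives their direction and scale, and their medians were -0.03, -0.02 and -0.02. How that table was centred stays unknown.

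The arrays held 62976 spots, of which 61657 were not controls, for 60620 probes and 34963 genes or transcripts. Background was corrected with normexp (offset 50) on mean signals and median background, and log ratios were normalised within each array by loess with control spots at weight 0 (limma 3.58.1, R 4.3.3). No scaling between arrays was applied. Control spots and spots with an outlier flag were left out, and spots of 1 probe were averaged. No spot was saturated. Probes were kept where they were well above background in the mock or the OPDA channel on at least 2 of 3 arrays, which left 41070 probes. The brightest kept probe stood for each gene, and 22423 genes were tested. For the 16617 genes with 2 kept probes, the log2 changes of both correlated at 0.946 across genes, and 8 of 2020 called genes had probes of opposite sign. Among the named genes 4 had probes that differed by more than 1 on the log2 scale: HSP70B, HSP17.6A, DGR1 (-2.50 and -1.16) and BRU6 (-2.98 and -1.92). Differences of over 1.5 times were also found for RSL4, GRI and RHD6, and for HSP22.0 (5.70 and 5.08), ABCG40 (4.55 and 3.87), GSTU11 (2.98 and 2.24) and APX2 (2.46 and 1.68).

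The sign of the swapped array was turned before the fit. Each gene's change was tested with limma's lmFit and eBayes as the mean log2 ratio of 3 arrays against 0, with 2 residual and 6.13 prior degrees of freedom and Benjamini-Hochberg adjustment over all genes tested. The ratio is taken within an array, so mock and OPDA samples are paired by hybridisation. An exact sign-flip test of 3 arrays cannot go below p = 0.25 and was not used for single genes. Gene lists were tested against other genes with camera (preset correlation 0.01, and an estimated correlation) and for a shared direction with fry. With an estimated correlation camera's test rests on only the 2 residual degrees of freedom, so a loss there does not by itself show correlated genes. Of the called genes, 15 had a mock channel and 25 an OPDA channel not well above background on any array. The fold of such a gene is a lower bound, and the only one named is LBD29.

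Before the data were examined, 24 gene lists with 437 members, the tests, and the rule for named genes were fixed. A member whose symbol was not paired with its locus in the tables was set aside, which removed 32 and left 405. The rule names the 12 largest rises and 10 largest falls that passed, had a symbol and went 1 way on 3 arrays, the 3 members of each list with the smallest adjusted p, with members by size of change where fewer than 2 passed, and OPR3, COI1, HSFA2, HSP101, HSP17.6A, HSP70, HSP90.1, MBF1C, JAZ10, VSP2, MYC2, OPR1, CYP81D11 and GSTU19. Symbols came from the files and from an NCBI RefSeq table of assembly TAIR10.1, in which 29189 of 34963 identifiers, or 83.5%, were found. The probes were designed on TAIR10, per the file headers, so no coordinates are given. Probes that match several genes were counted but not named, and made up 33 of the called features.

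The chain was tested on simulated arrays for the comparison of OPDA with mock, with 200 of 22423 genes changed. A further small gene list was shifted by less, and its genes counted as true calls. Of 67 genes changed by 0.5 on the log2 scale 0 were recovered, of 67 changed by 1 there were 37 (55.2%), and of 66 changed by 2 there were 55 (83.3%). The median estimated sizes were 0.49, 1.00 and 1.99, and 1.07% of the calls were false. The simulation called 93 genes and the data 2615. The adjustment was therefore stricter in the simulation, and its recovery does not carry over to the data. The share of the largest changes that had to be recovered was lowered after a first simulation fell short of it. Alternatives changed the background correction, offset, normalization, filter, probe choice, dye term, model, variance model, source of values, threshold and replicates, 1 at a time.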

Results

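Transcript levels were compared between Arabidopsis thaliana seedlings held for 1 h in liquid with 50 µM 12-oxo-phytodienoic acid (OPDA) and seedlings held for 1 h in a mock solution. OPDA is a reactive electrophilic oxylipin, and in wild-type plants the reductase OPR3 carries it towards jasmonic acid, whose active conjugate is perceived by the receptor COI1. All seedlings were opr3-3 coi1-1 double mutants, so the comparison asks which transcripts respond to OPDA in plants that carry mutations in both the OPR3 step and the COI1 receptor. The series' title places this question in the setting of thermotolerance. Each of 3 two-colour arrays carried RNA of 20 mock seedlings in one dye and of 20 OPDA seedlings in the other, at 9 days of age, and the dyes were exchanged on replicate 2. The median spot signal was 280.5 in the mock channel and 370.2 in the OPDA channel on replicate 1, 277.3 and 192.3 on replicate 2, and 188.5 and 175.7 on replicate 3. Between 64.6% and 70.5% of spots lay well above background in a channel. The number of arrays, 3, limits the precision of every value below. The labels number the samples but do not say that they came from separate sowings, so the p-values measure the spread between these samples, which may be technical.

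OPDA raised 1721 genes and lowered 894 of the 22423 tested, which is 11.7% of them (limma, adjusted p under 0.05). The rises were larger: 576 genes rose and 129 fell by at least 2-fold, and 73 rose by at least 8-fold. The small heat shock protein gene HSP22.0 (AT4G10250) rose by 5.70 ± 0.21 on the log2 scale (SD, n = 3; 52.1-fold), and CYP81D11 (AT3G28740), a cytochrome P450 gene of the detoxification response, by 5.38 ± 0.26 (41.7-fold). The 12 largest rises among genes with a symbol also held HSP21, HSP70B, HSP17.4, HSP18.2 and HSP17.6II, the zinc finger gene SAP10, the ABC transporter gene ABCG40, the low-sulfur response genes LSU1 and LSU3, and the sulfate assimilation gene APR3. These 12 ranged from 16.1-fold to 52.1-fold. AT1G52560 had the largest rise of all, 61.5-fold. It was fixed beforehand as a member of the small heat shock protein list and set aside for its symbol. It is named here, outside the rule, after its value was seen. Among genes with a symbol, the largest fall was that of BRU6 (AT4G37390), an auxin-inducible GH3 family gene, by 2.98 ± 0.66 on the log2 scale (7.87-fold lower). DGR1 (5.64-fold lower) and the tetraspanin gene TET12 (5.27-fold lower) came next. UNE11, GRI, CYP718, the metacaspase gene MC6, the nutrient response regulator HRS1, and the root hair genes RSL4 and EXPA7 completed the 10 largest among genes with a symbol. These were between 3.35-fold and 4.14-fold lower. Second probes gave smaller falls for BRU6 (-1.92 against -2.98 on the log2 scale), DGR1 (-1.16 against -2.50), RSL4 (-1.11 against -1.87) and GRI (-1.29 against -2.05). In the deposited value table, 1459 genes rose and 1200 fell, a more even split, and with Agilent's processed signals 690 rose and 337 fell by at least 2-fold. At adjusted p under 0.01, 1098 genes rose and 430 fell.

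**Figure D1:**
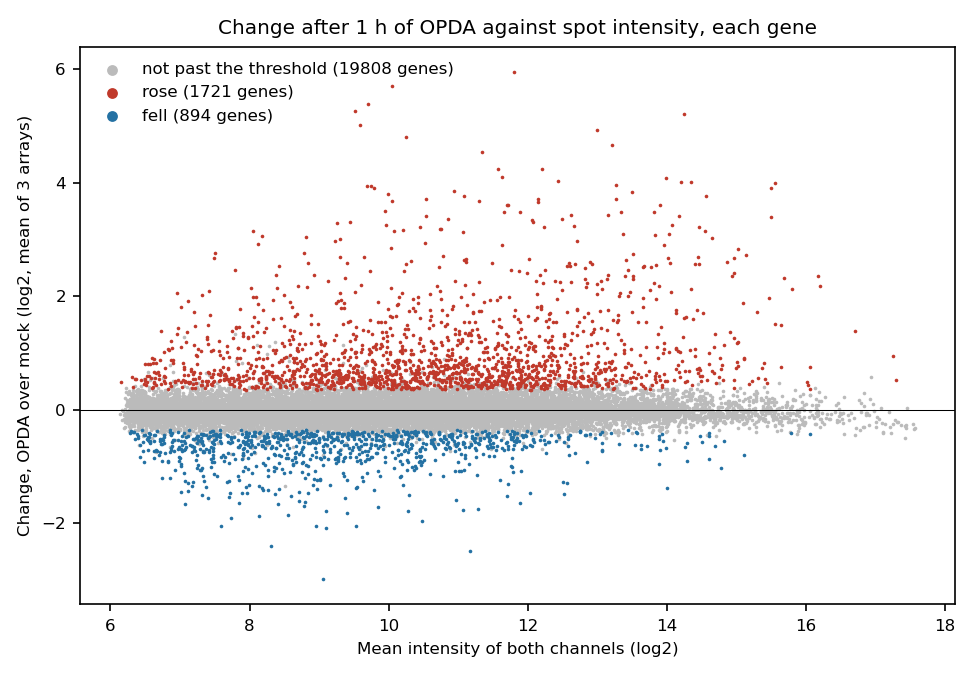
Each point is 1 of the 22423 genes tested; the x axis is the mean log2 intensity of both channels and the y axis the log2 change, OPDA over mock, as the mean of 3 arrays. The 1721 genes that rose (red) reach higher than 5 on the log2 scale, while the 894 that fell (blue) stay above -3, with the genes that did not pass the threshold in grey.

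**Figure D2:**
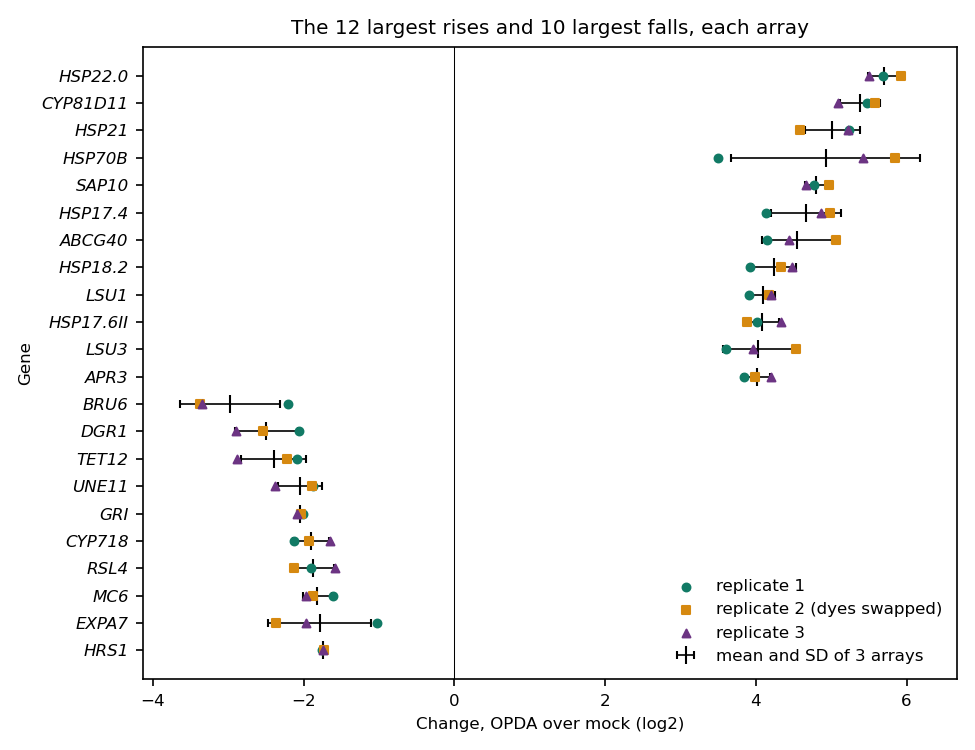
Log2 change, OPDA over mock, of the 12 largest rises and 10 largest falls among genes with a symbol. Each array has 1 marker (replicate 2 had the dyes exchanged), beside the mean with its SD over 3 arrays. The 3 arrays lie on the same side of 0 for each gene, and the SD is widest for HSP70B, at 1.25.

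Heat shock genes rose. Small heat shock proteins hold unfolding proteins in a soluble state. All 6 that were not set aside for their symbols rose, from 6.57-fold for HSP17.6A to 52.1-fold for HSP22.0. Their median was 4.45 ± 0.30 on the log2 scale (SD of the medians of 3 arrays). With the members set aside included, 16 of 18 rose, 1 fell and 1 did not pass, and the median was 3.83 ± 0.225. AT1G52560, with the largest rise of all, is among those set aside. Of 23 chaperones, 12 rose and 11 did not pass. The disaggregase gene HSP101 (AT1G74310) rose by 3.77 ± 0.08 (13.6-fold), HSP70T-2 by 3.97 ± 0.26 (15.6-fold), HSP70 (AT3G12580) by 2.32 ± 0.25 (5.00-fold) and HSP90.1 (AT5G52640) by 2.17 ± 0.08 (4.51-fold). Of 13 co-chaperones and thermotolerance factors, 10 rose, among them BAG6 (13.1-fold), FES1A (6.36-fold), HOP3 (5.98-fold) and the heat response coactivator MBF1C (4.39-fold). Of 19 heat shock factors, the transcription factors of these genes, 10 rose and 9 did not pass. HSFA2, an amplifier of the heat response, rose by 2.46 ± 0.27 (5.50-fold), HSFB2A was 3.40-fold and HSFA7A 3.37-fold higher. Adjusted over the list alone, 6, 16, 11 and 14 members of these lists rose, and 1 heat shock factor fell. Against all other genes (limma's camera, preset correlation) the adjusted p was 5.19e-16, 2.02e-11, 1.51e-15 and 1.19e-09 for the 4 lists, and the adjusted p was 0.117, 0.136, 0.136 and 0.125 with an estimated correlation. Different probes gave different sizes for HSP70B (4.93 and 5.94 on the log2 scale) and HSP17.6A (2.72 and 4.30).

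Most genes of protein folding in the endoplasmic reticulum and of the proteasome did not pass. Of 18 unfolded protein response genes, 3 rose and 15 did not pass: the DnaJ co-chaperone gene ERDJ3A rose 5.53-fold, and the transcription factor genes BZIP60 and BZIP28 rose 1.49-fold and 1.35-fold. The list's median log2 change was 0.10 ± 0.13, with 3 members past the threshold when adjusted over the list alone, a camera adjusted p of 0.039, and an adjusted p = 0.35 with an estimated correlation. Without replicate 3, and with Agilent's processed signals, 1 member passed, and BZIP28 and BZIP60 were also lost without replicate 1 (adjusted p 0.116 and 0.051). Of 17 proteasome genes, RPN6 rose 1.43-fold and 16 did not pass (1 also when adjusted over the list alone, camera adjusted p 0.379). RPT3 was at 1.26-fold, adjusted p 0.157. Without replicate 3 the count was 0, and the list median of 0.05 turned to -0.031 with Agilent's processed signals and to -0.087 in the value table.

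Genes of electrophile detoxification rose. Of 24 measured members of the detoxification list, 19 rose and 5 did not pass, with a median of 2.22 ± 0.26 on the log2 scale (4.65-fold). After CYP81D11, the glycosyltransferase gene UGT73B4 rose by 3.93 ± 0.18 (15.3-fold), the transcription factor gene ANAC032 by 3.19 ± 0.14 (9.11-fold), and OPR1 (AT1G76680), a reductase related to OPR3, by 3.40 ± 0.25 (10.6-fold). Of 35 glutathione S-transferases, which conjugate electrophiles to glutathione, 22 rose and 13 did not pass. GSTU24 rose by 3.84 ± 0.32 (14.3-fold), GSTU11 by 2.98 ± 0.10 (7.86-fold), GSTU1 by 2.58 ± 0.05 (5.96-fold) and GSTU19 by 2.36 ± 0.44 (5.13-fold), and the list median was 0.65 ± 0.04. Adjusted over the list alone, 19 detoxification genes and 23 glutathione S-transferases rose and 1 of the latter fell. The camera adjusted p was 1.38e-24 and 1.92e-17, and the adjusted p was 0.117 for both with an estimated correlation.

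Sulfur, redox and mitochondrial genes changed in part. Of 16 sulfate assimilation and glutathione synthesis genes, 7 rose and 9 did not pass. APR3 and APR1, which encode reductases of activated sulfate, rose by 4.01 ± 0.18 (16.1-fold) and 2.51 ± 0.10 (5.71-fold), and SERAT2;1, of cysteine synthesis, by 2.57 ± 0.36 (5.92-fold). Of 20 antioxidant enzymes and thioredoxins, 4 rose and 16 did not pass. The glutaredoxin gene GRX480 rose 12.8-fold, the dehydroascorbate reductase gene DHAR2 9.40-fold, the ascorbate peroxidase gene APX2 5.50-fold, and the glutathione reductase gene GR1 1.42-fold. Of 7 mitochondrial stress genes, 4 rose: NDB2 (3.37-fold), SRO5 (3.32-fold), the alternative oxidase gene AOX1A (2.26-fold) and ANAC013 (1.49-fold). GR1 was lost without replicate 2 (adjusted p 0.0795). GR1 and ANAC013, like other members of small counts given in the text outside the rule for named genes, were picked out after their values were seen. Adjusted over the list alone, 8, 5 and 5 members rose and 1 sulfate member fell. The list medians were 0.29 ± 0.04, 0.09 ± 0.13 and 0.58 ± 0.09 on the log2 scale. The camera adjusted p was 5.8e-05, 0.000839 and 7.59e-05, and the adjusted p was 0.136, 0.248 and 0.248 with an estimated correlation.

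Jasmonate genes changed in both directions. OPR3 (AT2G06050), mutated in these plants, gave a signal that rose by 2.15 ± 0.48 on the log2 scale (4.43-fold), and its second probe rose by 1.85. COI1 (AT2G39940) was at 0.14 ± 0.37 (adjusted p 0.646). Without wild-type samples, and with the place of the probes relative to the mutations not analysed here, neither gene checks the labels. Of 26 genes of jasmonate synthesis, catabolism and perception, 7 rose, 1 fell and 18 did not pass. KAT2, of beta-oxidation, rose 1.51-fold, and CYP94C1, of jasmonate catabolism, was 1.54-fold lower. In a fit of the separate channels CYP94C1 was at -0.62 on the log2 scale and did not pass (adjusted p 0.0659). Of 11 JAZ repressors, which are rapid targets of jasmonate signalling, JAZ7 (1.76-fold), JAZ3 (1.45-fold) and JAZ5 (1.34-fold) rose, JAZ4 fell (1.70-fold lower), and 7 did not pass. JAZ10 was at 0.56 ± 0.42, adjusted p 0.0513, and passed under other settings, such as a dye term (adjusted p 0.0252). Of 14 jasmonate response markers, the transcription factor genes MYC2 (1.42-fold) and ERF1 (1.32-fold) rose, MYC4 fell by 0.38 on the log2 scale, and 11 did not pass. VSP2, a storage protein gene often used as a jasmonate marker, was at 0.10 ± 0.74, adjusted p 0.86. Without replicate 1 the 3 counts were 5, 2 and 0, and JAZ3, JAZ5, MYC2, ERF1 and MYC4 no longer passed. JAZ5 was also lost without replicate 3, and ERF1 and MYC4 without any 1 of the 3 replicates, and the second probe of MYC4 gave 0.039. Median centring gave 4, 2 and 1, and Agilent's processed signals gave 5 for the synthesis list and 0 for the markers.

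Adjusted over the list alone, 10 synthesis genes, 5 JAZ genes and 4 response markers rose, and 1 of each list fell. The median log2 changes of the 3 jasmonate lists were 0.14 ± 0.12, 0.32 ± 0.19 and 0.09 ± 0.18. The camera adjusted p was 0.000839, 0.0207 and 0.108, and the adjusted p was 0.415, 0.442 and 0.442 with an estimated correlation.

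Regulators of rapid stress responses rose, while other hormone lists were mixed. Of 24 rapid stress and wound regulators, 17 rose, WRKY53 fell and 6 did not pass. DREB2A, a transcription factor gene of the heat and drought response, rose by 3.43 ± 0.18 (10.8-fold), the zinc finger gene ZAT12 by 3.22 ± 0.21 (9.34-fold) and DREB2B by 1.55 ± 0.15 (2.93-fold). Of 15 abscisic acid and dehydration genes, ABI2 (3.67-fold), ABF3 (2.44-fold), HAI1 (2.23-fold) and NCED3 (1.88-fold) rose, and RD29A and LEA4-5 fell by 0.59 and 0.56 on the log2 scale, while 9 did not pass. ABI2 and HAI1 encode phosphatases that restrain abscisic acid signalling, and NCED3 an enzyme of its synthesis. Of 13 salicylic acid genes, PR1 (1.95-fold) and ICS1 (1.52-fold) rose and 11 did not pass. Without replicate 1, WRKY53 and LEA4-5 no longer passed (adjusted p 0.254 and 0.0947), and with Agilent's processed signals 1 salicylic acid gene passed. WRKY53 was also lost under several other settings, among them Agilent's processed signals (adjusted p 0.0803), a dye term (0.0542) and its second probe (0.0574). RD29A was lost with Agilent's processed signals (adjusted p 0.0554) and with median centring (0.0568). Of 20 camalexin and glucosinolate genes, the camalexin genes PAD3 (1.67-fold), CYP71A13 (1.43-fold) and CYP71A12 (1.38-fold) rose, MYB34, a regulator of indole glucosinolates, fell by 0.46 on the log2 scale, and 16 did not pass. Without replicate 1, 1 member of that list passed, and with Agilent's processed signals 2 did. CYP71A12 and CYP71A13 were lost without replicate 1 or 2, as was MYB34.

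Adjusted over the list alone, 19 stress regulators rose and 1 fell, 5 abscisic acid genes rose and 2 fell, 2 salicylic acid genes rose, and 3 camalexin and glucosinolate genes rose and 1 fell. The list medians were 0.87 ± 0.27, 0.18 ± 0.22, 0.09 ± 0.09 and 0.01 ± 0.09 on the log2 scale. For the last list camera pointed down while the median and the mean (0.01) lay above 0. The camera adjusted p was 4.48e-15, 0.00837, 0.211 and 0.83, and the adjusted p was 0.136 and 0.248 for the first 2 with an estimated correlation.

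Many auxin response genes and root markers fell. Of 15 auxin response genes, 9 fell and 6 did not pass. LBD16, of lateral root formation, fell by 0.93 ± 0.12 on the log2 scale (1.90-fold lower) and the repressor gene IAA2 by 0.60 ± 0.07 (1.51-fold lower). LBD29 was not well above background in the OPDA channel and was at least 1.72-fold lower, adjusted p 0.00348; the bound sets the mean of normalised mock signals against, for each array, the higher of the lowest signal well above background and the probe's own. Of 9 root markers, 5 fell: EXPA7 (3.45-fold lower), RHD6 (-1.07 on the log2 scale) and COBL9, which are root hair genes, and the transporter genes PHT1;4 (2.94-fold lower) and NRT2.1 (2.04-fold lower). The other 4 root markers, PYK10, BGLU22, IRT1 and SCR, did not pass, at 0.24, 0.10, 0.25 and -0.19. A second RHD6 probe gave -0.30, adjusted p 0.199, and COBL9 was lost without replicate 2 (adjusted p 0.0627). Of these lists, 12 auxin genes and 5 root markers fell when adjusted over the list alone. The list medians were -0.47 ± 0.16 and -0.69 ± 0.42. The camera adjusted p was 9.27e-09 and 0.000839, and the adjusted p was 0.26 and 0.382 with an estimated correlation.

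The 25 photosynthesis genes, taken as shoot markers, had a median of -0.25 ± 0.28, and 0 passed in the limma fit, with 7 at an unadjusted p under 0.05. RBCS2B was at -0.50 ± 0.59 and LHCB1.2 at -0.41 ± 0.28. Without replicate 2, 8 of them passed, all lower in OPDA, without replicate 1 it was 1, and with median centring 2. The 10 cell cycle genes had a median of -0.15 ± 0.17, and 0 passed, with 1 at an unadjusted p under 0.05. CYCA1;1 was at -0.27 ± 0.27, and without replicate 2 it alone passed. PCNA1 was at -0.26 ± 0.21. Of 9 clock genes, with a median of 0.19 ± 0.07, PRR5 rose 1.41-fold, 8 did not pass, and 2 passed without replicate 2. PRR9 was at 0.32 ± 0.12. Of 8 genes often used as references, the glycolytic gene GAPC1 rose by 1.39 ± 0.40 (2.63-fold) and UBQ10 by 0.52 ± 0.30 (1.43-fold). UBQ10 was lost without replicate 2 and with median centring (0.37, adjusted p 0.184). The reference list had a median of 0.09 ± 0.03, which was -0.063 in the value table. When adjusted over the list alone, 0 photosynthesis, 0 cell cycle, 1 clock and 2 reference genes passed. The camera adjusted p was 5.89e-05, 0.0291, 0.0207 and 0.085 for the 4 lists, and the adjusted p was 0.442, 0.442 and 0.257 for the first 3 with an estimated correlation.

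In fry, which tests whether the genes of a list moved on balance 1 way without setting them against other genes, 12 of the 24 lists passed, all of which also passed in camera with the preset correlation. These were the 4 heat shock lists, with adjusted p from 0.00267 to 0.00401, both detoxification lists (0.00318 each), the sulfate (0.00713), antioxidant (0.0148) and mitochondrial (0.0231) lists, the stress regulators (0.00987), the abscisic acid genes (0.0499) and the clock (0.0428). Another 7 lists passed in camera and not in fry: auxin response (0.0531), the unfolded protein response (0.0648), root markers (0.107), jasmonate synthesis (0.145), cell cycle (0.254), JAZ repressors (0.257) and photosynthesis (0.257). Where the members set aside were kept in the lists, auxin response (0.0496) and the proteasome (0.0424) also passed in fry. The auxin list itself was the same in both, so its outcome turned on the adjustment over the lists. Tested for change in either direction, 22 lists passed in fry, and the cell cycle and photosynthesis lists did not (0.258 each). The 22 include the reference genes (0.0254), of which 6 of 8 did not pass singly, and the proteasome (0.0449), of which 16 of 17 did not. A pass in this form therefore does not by itself mark a list as responding to OPDA.

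**Figure D3:**
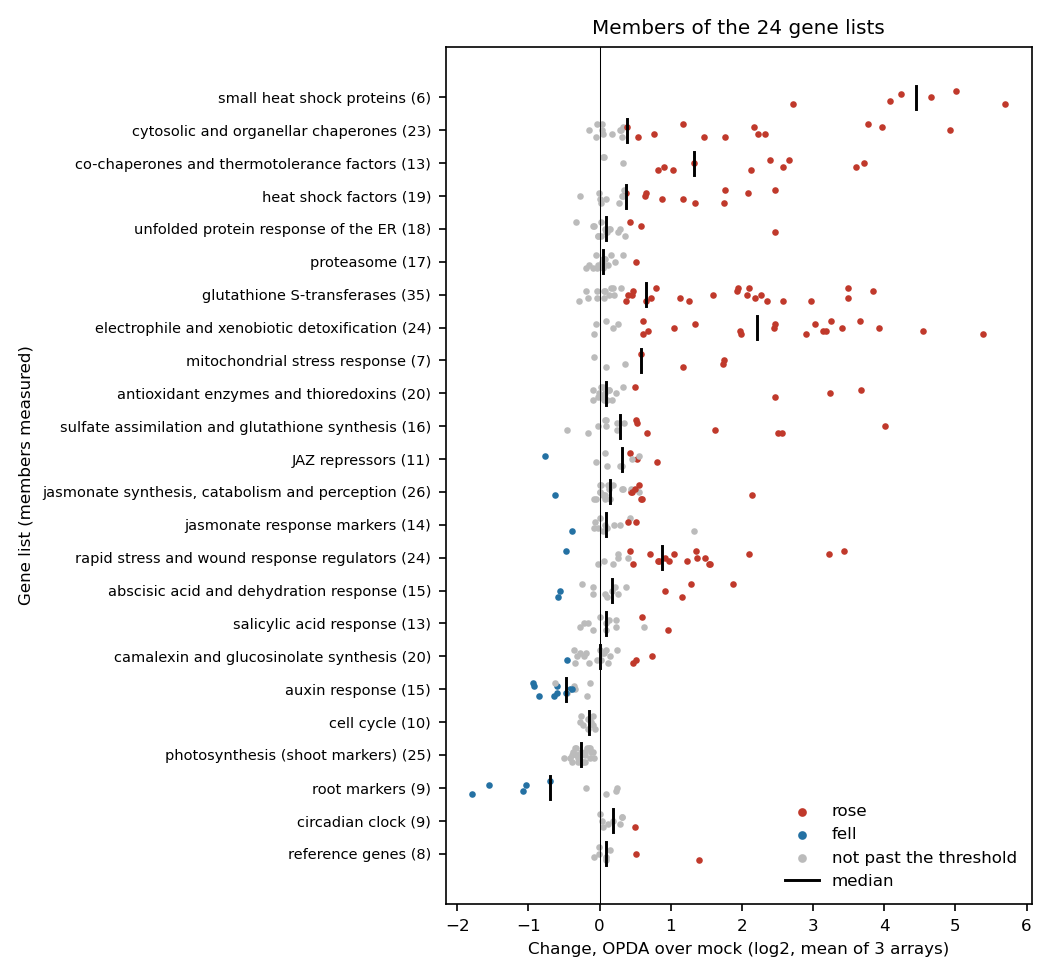
Log2 change, OPDA over mock (x axis, mean of 3 arrays), of each measured member of the 24 gene lists, without the members set aside. The y axis gives the lists, with the number of measured members in parentheses. Members that rose are red, members that fell blue and the others grey, with a bar at the list median. The small heat shock proteins have the highest median, 4.45, and the root markers the lowest, -0.69.

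The log2 change of OPDA over mock correlated at 0.80 between replicates 1 and 3, at 0.71 between 1 and 2, and at 0.73 between 2 and 3 (Pearson's r across genes, which are not independent replicates). Spearman's rho, which large changes weigh on less, was 0.58, 0.29 and 0.41 for the same pairs. Before the sign of the array with exchanged dyes was turned, its correlations with the others were -0.71 and -0.73. The dyes lay 1 way on 2 arrays and the other way on 1, so a gene-specific dye effect does not cancel in the reported mean. Replicates 1 and 3, the pair that correlated best, share the dye orientation. A dye term was past the threshold for 20 genes, 1 of them among the called genes, and for 2420 genes at an unadjusted p under 0.05. The latter is more than chance alone would leave among 22423 genes. The fit with a dye term has fewer residual degrees of freedom than the reported fit, so dye effects beyond the 20 genes can be missed. With that term, 1991 genes rose and 1127 fell, and 2591 of the 2615 called genes were called in both fits.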

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

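The settings that took the second probe of a gene, that kept all fixed list members, and that repeated the dye fit under other settings were chosen after seeing the data. Over the alternatives on all genes, 2026 to 3118 genes passed, with 650 to 1027 at 2-fold or more, apart from 1528 at adjusted p under 0.01, and 1862 and 468 with the second probe, which only 16617 genes have; with 2 of the 3 arrays it was 2148 to 2924 and 688 to 738. No gene called both in the reported fit and in an alternative changed sign, except 1 with the second probe. Of 109 genes followed, 83 kept their call in every fit that gave them a value, and 16 lost it when an array was left out. MYC4 turned to 0.039 with the second probe. Of 24 lists, 19 passed in camera with the preset correlation and 0 with an estimated one. The second form rests on only 2 residual degrees of freedom, so this loss does not by itself show correlated genes. For the heat shock factors the estimated correlation was -0.0336, below the preset 0.01, yet camera's unadjusted p went from 3.47e-10 to 0.0208. Other lists had estimates well above the preset. The highest were 0.615 for photosynthesis, 0.498 for JAZ repressors, 0.471 for root markers, 0.464 for auxin response, 0.434 for the cell cycle and 0.301 for jasmonate synthesis. If these estimates hold, camera's p with the preset correlation is too small for those lists, which also did not pass in fry. With Agilent's processed signals the number of members past the threshold was 1 for the unfolded protein response, 0 for the proteasome, 5 for jasmonate synthesis, 0 for jasmonate response markers, 1 for salicylic acid, 2 for camalexin and glucosinolate synthesis and 0 for the clock, and the proteasome median was -0.031. With median centring of each array it was 1 for the unfolded protein response, 0 for the proteasome, 2 for JAZ repressors, 4 for jasmonate synthesis, 1 for jasmonate response markers, 2 for photosynthesis, 0 for the clock and 1 for reference genes, and the lowest correlation between arrays was 0.65. In the series value table it was 1 for the unfolded protein response and 0 for the proteasome, and the medians of the proteasome, camalexin and glucosinolate, and reference lists were -0.087, -0.0925 and -0.063. Reference genes past the threshold were 1 with no filter on dim probes and 1 in eBayes with trend and robust, unfolded protein response genes 5 with a dye term, jasmonate response markers 5 when adjusted over the list alone, and small heat shock proteins 17 with all fixed members, a larger list. The dye effect was past the threshold for 0 genes with Agilent's processed signals, 0 with offset 10, 0 in the series value table, 197 with median centring, 43 with scale and Aquantile between arrays, 58 with no filter and 7 with the mean of a gene's probes, against 20. Leaving out each array in turn gave 1 to 3 unfolded protein response genes, 0 to 1 proteasome genes, 2 to 6 JAZ repressors, 5 to 9 jasmonate synthesis genes, 0 to 3 jasmonate response markers, 1 to 4 camalexin and glucosinolate genes, 0 to 1 cell cycle genes, 0 to 8 photosynthesis genes, 1 to 2 clock genes, 1 to 2 reference genes, and a lowest correlation between arrays of 0.71 to 0.80. Fits without 1 array hold fewer samples; for the other differences the cause was not tested. A slide block was not run, since all arrays lay on 1 slide. The reported fit, of ratios within arrays, is itself paired. Signal over background limits the lower end: 15 called genes in the mock channel and 25 in the OPDA channel have only a bound.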

Other observations

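The gene families, the comparison of probe sequences, the leaving out of root hair genes already seen, the split by mock level and the test on other scalings of the arrays were chosen after the data were seen. Genes were grouped by the family named in the array's descriptions, and 167 families of at least 10 tested genes were compared with all other genes for a surplus of risen or of fallen members (one-sided Fisher's exact test, adjusted over both directions of all families; genes are not independent). The test passed for 16 families. Of 95 tested genes of the cysteine/histidine-rich C1 domain family, which encode proteins with zinc-binding domains, 31 fell and 0 rose in limma, with a median log2 change of -0.27 (adjusted p 7.28e-18). AT5G54040 fell by 1.96 ± 0.04 on the log2 scale (SD, n = 3; 3.90-fold lower) and AT5G02350 by 1.85 ± 0.11 (3.60-fold lower). Between 29 and 39 members fell and 0 rose under 6 other scalings of the arrays, and 25 to 35 fell on leaving out an array, with 1 risen without replicate 2 and 1 without replicate 3. Of the 95 probes, 6 shared a stretch of 20 bases with another probe of the family, and of the 89 genes without one 29 fell, or 32.6%, against 3.99% of all genes. Probes were compared with each other and not with the transcripts of related genes. A probe that also reads other members of the family is therefore not excluded.

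Of 12 tested genes of the CAP superfamily, 7 fell (median -0.58, adjusted p 1.74e-05), and 5 to 7 did under the other scalings and on leaving out an array. Of 49 genes of the SAUR-like auxin-responsive family, 11 fell (median -0.16, adjusted p 0.000308), while 7 fell without replicate 1 and 7 without replicate 3, and 1 rose without replicate 2. Of 10 genes that the descriptions group as glutamate receptors 2, which include GLR2 and GLUR2 beside the GLR2 clade, GLR2.2, GLR2.3, GLR2.1 and GLR2.6 fell by 1.04, 0.74, 0.64 and 0.61 on the log2 scale (adjusted p 0.0145 for the group), and a second GLR2.6 probe gave -0.29, adjusted p 0.202. A surplus of falls was also found for leucine-rich repeat protein kinases (15 of 93 fell, 1 rose), peroxidases (10 of 48, 3 rose), cytochromes P450 (19 of 167, 22 rose), 1 of 2 labels of the invertase and pectin methylesterase inhibitors (5 of 18, 1 rose), pectin lyase-like proteins (8 of 55, 3 rose) and UDP-glycosyltransferases (8 of 57, 6 rose). The other label of the inhibitors had 4 of 21 fallen and 2 risen (adjusted p 0.13), and 2 smaller labels of leucine-rich kinases had 1 of 11 fallen each (adjusted p 1). Leucine-rich repeat kinases that fell numbered 9 with median centring, 9 without replicate 1 and 9 without replicate 3. Fallen UDP-glycosyltransferases numbered 3 with median centring, 3, 5 and 4 without replicates 1, 2 and 3, fallen pectin lyase-like genes 5 without replicate 3, and fallen peroxidases 6 with Agilent's processed signals. Of 32 genes described as glycine-rich proteins, 10 rose (median 0.16, adjusted p 0.00344), and in the value table, 9 rose and 1 fell. A surplus of rises was also found for HSP20-like chaperones (9 of 25 rose, 1 fell), RING/U-box proteins (30 of 182, 15 fell), protein phosphatases 2C (11 of 48, 4 fell), VQ motif proteins (7 of 22, 3 fell) and MATE efflux proteins (9 of 39, 2 fell). With Agilent's processed signals 17 RING/U-box and 4 VQ genes rose, and without replicate 2 11 VQ genes did. The medians of the HSP20-like, RING/U-box and phosphatase families lay near 0 and changed sign between scalings. Of 43 tested microRNA transcripts 7 rose, among them MIR168a (2.15-fold) and MIR824 (2.13-fold), and of 202 long intergenic non-coding RNAs 9 rose and 2 fell.

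Besides the root markers, 24 root hair genes and 22 genes of other root cell layers were listed, and RSL4, RHD6, EXPA7 and COBL9, already known to fall, were left out of the tests; of the other 18 measured root hair genes 9 fell and CSLD3 rose, with a median of -0.37 (with the 4 it was 13 of 22 and -0.60). The median of the 18 was -0.55 on the array with exchanged dyes and -0.27 and -0.42 on the others, which argues against a dye bias of these genes. The other root layers had a median of -0.30 (-0.19, -0.31 and -0.39 on replicates 1, 2 and 3), with 5 of 17 fallen and GPAT5 risen. A smaller share of root tissue in the OPDA samples stays open. These medians are within the margin of 0.3 set beforehand of those of the 18 genes on each array. On replicate 1 that margin is larger than the change of the 18 genes (-0.27), so root layers without any change would also have met it. On replicate 2 the medians are not within the margin when the 4 genes are kept (-0.68), so the outcome turns on a choice made after the data were seen. PYK10 and BGLU22, strongly expressed in roots, were at 0.24 and 0.10, and the photosynthesis genes, which such a share would raise, at a median of -0.25 ± 0.28, too few or too spread to decide, and no fall particular to root hairs was shown.

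Rises of at least 2-fold outnumbered falls, 576 to 129, or 4.47 for each fall. If falls of genes dim in mock were hidden by the background, genes bright in mock would show a more even split. Of the genes above the median of the mock channel, however, 304 rose and 49 fell past the threshold, 6.20 for each fall. On single arrays, with all genes above that median counted whether called or not, it was 6.33, 3.99 and 3.62 on replicates 1, 2 and 3. A split by the mean of both channels gave 11 for each fall among the brighter genes, but a rise itself moves a gene into that group, so this value decides nothing. The 6 other scalings of the arrays include changes of the background step. The lowest number was 2.05 for each fall, with Agilent's processed signals, which also differ in dye normalization. It was 3.04 with offset 10 and 3.78 with no background correction. Median centring gave 3.91, scale and Aquantile between arrays 4.54, and the deposited series values 3.70, against 4.47 in the reported fit. The lowest numbers thus came with another background step, and the part of background correction and its offset in the size of the imbalance stays open. Each of these settings also centres the log ratios near 0, and the part of centring stays open. The mock split argues only against hidden falls of genes dim in mock as the whole cause. No biological explanation was tested.

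The 3 arrays have 4 sign patterns, counting a pattern and its mirror once, which are too few for a share under 0.05. The real pattern gave 2615 genes and the highest of the others 0, and for changes of at least 2-fold 705 and 0, and for members of the 24 lists 160 and 0. At an unadjusted p under 0.05 in limma the real pattern gave 5179 genes, and turning replicate 1, 2 or 3 gave 185, 792 and 135. Turning an array moves changes shared by the arrays into the residual spread. The counts of 0 thus follow from the correlation between arrays and are not counts to be had by chance. Turning replicate 2 sets one dye against the other in the same order on all 3 arrays, so its 792 genes can hold dye effects.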
